A study of Homo sapiens with 27 samples.

How the data were processed

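RNA sequencing libraries were analysed from 3 cell types differentiated from the human embryonic stem cell line H9, which the labels give as the starting line of all 27 libraries. Vascular endothelial cells (EC, 9 libraries), neural stem cells (NSC, 6 libraries) and vascular smooth muscle cells (VSMC, 12 libraries) had been cultured on a flat surface (2D), in a polyethylene glycol (PEG) hydrogel or in an alginate hydrogel. The labels place the libraries in 9 groups of 3, and smooth muscle cells from alginate form 2 of these groups, from day 1 and day 6. The titles give no culture day for the other groups. The names of some deposited files carry a day, which the titles do not settle. Those of the smooth muscle cells carry day 6 for 2D and day 1 for PEG, those of endothelial cells day 6 for 2D only and those of neural stem cells day 6 for alginate only. Names of alginate files carry the word fiber, whose meaning is not given in the sources used here. Time in culture may therefore differ between the groups of a comparison, so that a difference between a hydrogel and 2D, or between hydrogels, may hold an effect of time. Per the labels' protocols, total RNA was isolated on Qiagen columns with DNase treatment on the column, TruSeq RNA v2 libraries were made, and 15 libraries (endothelial and neural stem cells) ran on 1 lane and the other 12 (smooth muscle cells) on another. The lane therefore cannot be told apart from the cell type wherever smooth muscle cells were compared with endothelial or neural stem cells, whereas each comparison of culture systems lay within 1 lane.

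The deposited files hold raw counts of reads per gene symbol, 1 file per library, with no normalisation. The submitters' processing notes name Bowtie, HTSeq and the genome build hg19, and the versions, the gene annotation and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping genes and of antisense partners cannot be separated, and reads of near-identical genes (histones, ribosomal proteins with their pseudogenes, actins, FAM153C, NBPF7 and HSPA6 among those named) may be divided between copies. Each file listed 23368 gene symbols, and 26 blank entries were left out of totals and tests. Counts were 0 in all libraries for 2770 genes. Totals per library ranged from 4091679 to 6954386 counts. No pair of libraries held identical counts (0 pairs), and replicate pairs differed by more than sampling noise, with median chi-square values over Poisson of 2.03 to 6.42 for genes of at least 1000 counts, so each library was counted once. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

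Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM normalisation, filterByExpr on the groups) in R 4.3.3, with Benjamini-Hochberg adjustment. Every adjusted p of a gene comes from this test. Comparisons within a cell type were fitted on all libraries of that type, with 13858 genes tested in endothelial cells, 13368 in neural stem cells and 14064 in smooth muscle cells. Cell types in 2D and the differences of culture effects between cell types were fitted on all 27 libraries with 15250 genes. The biological coefficient of variation was 0.0716, 0.0721, 0.0762 and 0.0741 in these 4 fits. A gene was called at an adjusted p under 0.05, and calls with a fold of at least 2 were counted beside. Levels are given as CPM (counts scaled to a common library size) after TMM normalisation over the 27 libraries, as mean ± SD with n = 3, and changes as log2 fold change ± standard error from the fit. A fold against a group with 0 counts was computed against a floor of 3 counts over the group and is written as at least that fold. With 1 to 3 counts over a group the ratio is given with its 95% counting interval. Intervals and floors cover counting error only, and the fitted fold changes of such genes depend on the prior count. So does a fold change without a library that held most counts of its group. Values without 1 library are given for called genes named by the rule below where they moved the fold by over 1.5 times, and were not computed for further members of lists.

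The tests of genes and lists, the 39 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from the later ones named as such. The lists cover cell type markers, processes and RNA quality. The list of mitochondrial transcripts had no measured member, which left 38 lists. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted within each comparison. The same test with a correlation estimated from the data is more cautious. It kept 71 of 268 calls, and the adjusted p it gave is printed wherever it exceeded 0.05. A count of list members that rose or fell is over the members tested. Where the count adjusted over the list alone differed, it is given too. Medians of lists with members at 0 counts in a group are also given with these members at their bound where that moved a called median by over 0.1.

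Named genes were the 6 with the largest rise and the 6 with the largest fall in the 6 main comparisons, and 3 each elsewhere, among genes called with at least 10 CPM in the higher group and with all 3 libraries of 1 group above all 3 of the other, which chance gives for 10% of genes. Some of these genes are not reported here. The tests of a difference between culture effects did not use this last condition. To these were added up to 4 called members per direction of each list in order of adjusted p, and the markers PECAM1, CDH5, KDR, PAX6, SOX1, NES, ACTA2, TAGLN, CNN1, POU5F1 and NANOG. NANOG was too low in all groups to be tested. Unnamed loci, small RNAs, genes with an antisense symbol ending in -AS and a digit, and sex-linked marker genes were left out. The genes of the process plot were chosen for display after their values were seen.

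Gene positions were looked up in GENCODE v29 on GRCh38, not on the build named by the submitters, and no position was converted. The scheme was tested on simulated counts with 200 changed genes. For the EC alginate comparison (13544 simulated genes) it recovered 62.7%, 74.6% and 97.0% of genes changed 1.5-fold, 2-fold and 4-fold, with 9 false calls. For NSC alginate (12567 genes) these shares were 56.7%, 85.1% and 90.9% with 7 false calls, and for VSMC alginate on day 6 (13896 genes) 62.7%, 68.7% and 90.9% with 6. Alternatives were RLE size factors, no filter and a stricter filter on low counts (CPM of 1 in 3 libraries), DESeq2 1.42.0, a block for the replicate number, other sets of libraries in the fit, each replicate left out in turn, fry in place of camera, and an estimated correlation. After the data were examined, a fit without 2 smooth muscle libraries that stood apart (PEG replicate 3 and day-1 alginate replicate 1), a count of undetected genes at 3 thresholds and a further measure of the share of endothelial transcript were added. Plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.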

Results

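In flat culture the 3 cell types were set apart by the marker genes of their lineages. CDH5 (VE-cadherin, the cadherin of endothelial junctions) stood at 340.2 ± 24.0 CPM in endothelial cells and 1.00 ± 0.20 CPM in neural stem cells, a log2 fold change of 8.37 ± 0.18 (adjusted p = 1.24e-40). KDR, a receptor for VEGF, stood at 2092 ± 30.5 against 29.7 ± 5.92 CPM (6.12 ± 0.08), and the junction gene PECAM1 was 796-fold higher in endothelial cells (95% counting interval 143 to 31476). The trunk HOX gene HOXB9, the membrane protein gene TM4SF1 and CYP1A1, an enzyme of xenobiotic oxidation, had 0 counts in neural stem cells and were at least 1955-fold, 1077-fold and 824-fold higher in endothelial cells. SOX2 and SOX1, transcription factors of neural progenitors, had 0 counts in endothelial cells. SOX2 was at least 1401-fold higher in neural stem cells, SOX1 stood at 8.24 ± 2.58 CPM there, and PAX6, an eye and forebrain transcription factor, was 1426-fold higher (487 to 6916). The neuropeptide gene ADCYAP1 and the histone gene HIST2H2BF, which has near-identical copies, were at least 602-fold and 613-fold higher in neural stem cells. NES, an intermediate filament gene used as a neural stem cell marker, was higher in endothelial cells (1.47 ± 0.05), and POU5F1, a pluripotency factor, was higher in neural stem cells (log2 fold change -5.19 ± 0.46, 16.0 ± 1.51 CPM in neural stem cells). POU5F1 had a log2 fold change of -5.19 with all libraries and -5.79 without EC 2D replicate 1, PAX6 -10.31 and -9.72 without EC 2D replicate 2 and -13.50 without EC 2D replicate 3, and PECAM1 9.27 and 11.47 without NSC 2D replicate 2.

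Of 28 endothelial genes 27 were higher in endothelial than in neural stem cells (median log2 fold change 6.58, and 6.14 with genes at 0 placed at their bound, camera adjusted p = 4.26e-10), among them FLT1 (11.45) and TEK (6.58). Of 15 genes of lateral mesoderm all 15 were higher (median 7.60, at the bound 6.11, adjusted p = 4.88e-09), for example HAND1, 797-fold higher (220.3 to 6585). The hindbrain and spinal list, which holds HOX genes that other trunk tissues also express, had 14 of 17 genes higher in endothelial cells (median 7.75, at the bound 4.75, adjusted p = 6.35e-06). Neural stem cells were higher in 16 of 18 neural stem genes (median -3.76, at the bound -2.58, adjusted p = 1.40e-06) and 12 of 14 forebrain genes (median -5.91, adjusted p = 3.12e-05), with SIX3 (-8.88) among the latter and FEZF1, which had 0 counts in endothelial cells and was at least 367-fold higher. All 8 histone genes measured were lower in endothelial cells (median -6.44, adjusted p = 1.76e-04). Of 24 hypoxia genes 22 were lower in endothelial than in neural stem cells in 2D, such as BNIP3 (-3.30) and HK2 (-3.81), with a median of -2.23 (adjusted p = 1.44e-07, but adjusted p = 0.144 with an estimated correlation). Between these cell types 11695 of 15250 genes passed the test (6070 higher and 5625 lower in endothelial cells), 7212 of them with at least a 2-fold difference.

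Smooth muscle cells in 2D differed from endothelial cells in contractile and endothelial genes. ACTA2 (smooth muscle alpha-actin, whose reads may be shared with other actin genes) stood at 741 ± 5.05 CPM against 117 ± 2.08 CPM in endothelial cells (2.67 ± 0.10, adjusted p = 2.91e-28). TAGLN (transgelin) stood at 1339 ± 10.5 against 391 ± 23.3 CPM (1.78 ± 0.08) and CNN1 (calponin) at 213 ± 9.64 against 55.3 ± 6.78 CPM (1.95 ± 0.12). Of 20 smooth muscle genes 15 were higher and 2 lower in smooth muscle cells, or 15 and 3 adjusted over the list alone (median 0.78, adjusted p = 1.59e-05). All 28 endothelial genes were lower (median -4.44, at the bound -4.18, adjusted p = 2.15e-21), with CDH5 at -5.64 ± 0.13 and KDR, still at 491 ± 10.2 CPM, at -2.09 ± 0.06. PECAM1 was 1019-fold higher in endothelial cells (183 to 40304). The gap junction gene GJA4, the phosphatase regulator PPP1R16B and ESM1, an endothelial proteoglycan, had 0 counts in smooth muscle cells and were at least 1147-fold, 413-fold and 385-fold higher in endothelial cells. DKK2, a modulator of Wnt signalling, was 402-fold higher in smooth muscle cells (71.7 to 15904), the neurotrophin receptor NTRK2 was higher there (6.22 ± 0.16), and DNM3OS, which lies opposite to another gene, was 87.7-fold higher (23.9 to 730.2). POU5F1 stood at 0.54 ± 0.15 and 0.41 ± 0.27 CPM in these groups (adjusted p = 0.727). Of 20 genes of the unfolded protein and ATF4 response 19 were higher in smooth muscle cells (median 1.04, adjusted p = 2.74e-12), for example HSPA5 (1.99) and DDIT3 (2.56). In all, 7034 genes passed the test (3508 higher, 3526 lower, 2078 by 2-fold), on cell types that ran on different lanes. DKK2 had a log2 fold change of 8.20 with all libraries and 10.09 without EC 2D replicate 1 and PECAM1 -9.54 and -11.45 without VSMC 2D replicate 3.

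Against neural stem cells, smooth muscle cells in 2D were higher in matrix genes. COL3A1, a fibrillar collagen, stood at 8971 ± 56.8 CPM against 1.20 ± 0.73 CPM (12.88 ± 0.12, adjusted p = 4.07e-57), and the proteoglycan gene LUM and HOXB9 had 0 counts in neural stem cells and were at least 1545-fold and 2320.5-fold higher in smooth muscle cells. ACTA2 (6.82 ± 0.16), TAGLN (2.68 ± 0.08), CNN1 (2.75 ± 0.13) and NES (1.86 ± 0.05) were higher too. SOX2 and the homeobox genes LHX5 and LMX1A had 0 counts in smooth muscle cells and were at least 1381-fold, 764-fold and 368-fold higher in neural stem cells. SOX1 was 133-fold higher there (23.4 to 5309.9), PAX6 differed by -9.16 ± 0.24 and POU5F1 by -4.83 ± 0.44. Of 22 genes of fibrillar collagen and matrix 18 were higher and 2 lower, or 19 and 2 adjusted over the list alone (median 4.08, adjusted p = 8.38e-09), and 16 of 18 neural stem genes were lower (median -4.19, at the bound -2.74, adjusted p = 2.01e-06). The 20 smooth muscle genes had 15 higher and 2 lower (median 2.42, adjusted p = 2.40e-04, with an estimated correlation adjusted p = 0.0597). In all, 11507 genes passed the test (5939 higher, 5568 lower, 7041 by 2-fold), again across lanes. SOX1 had a log2 fold change of -6.63 with all libraries and -8.53 without VSMC 2D replicate 3.

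**Figure D1:**
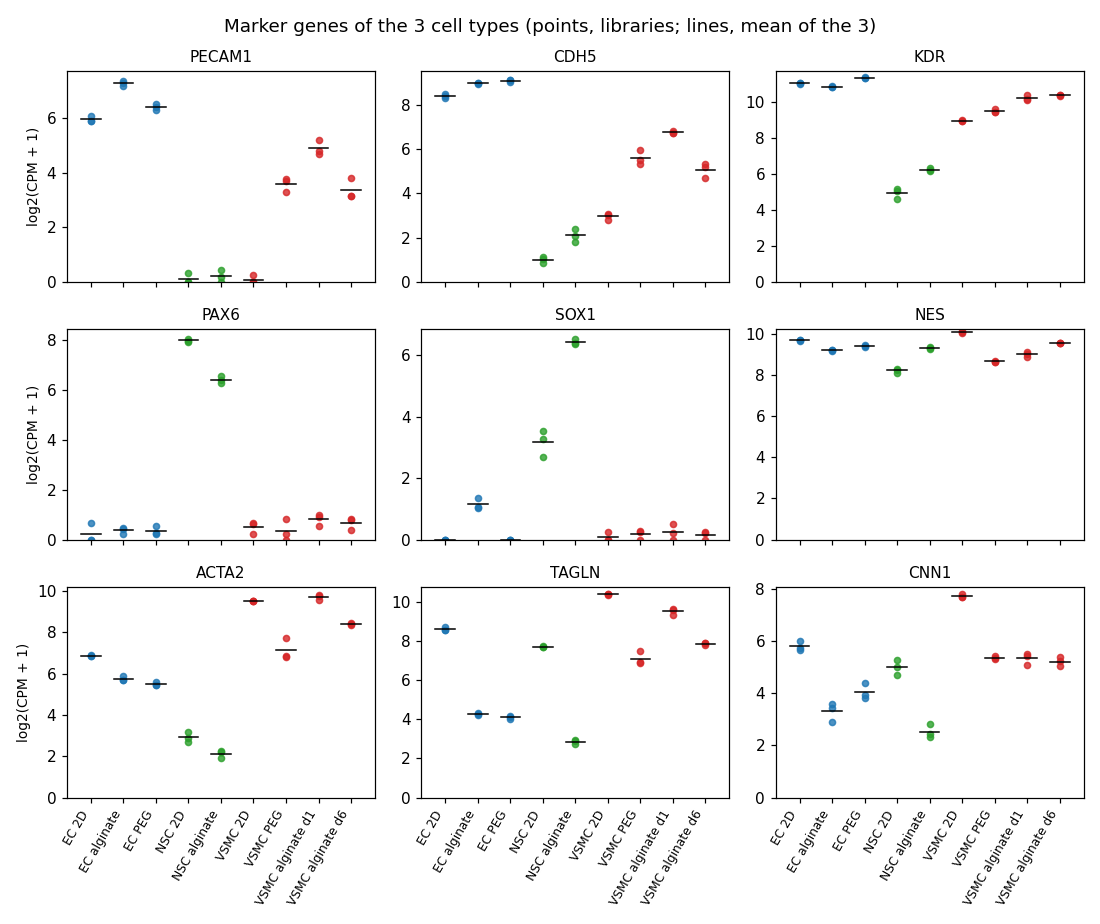
Levels of 3 endothelial (PECAM1, CDH5, KDR), 3 neural stem (PAX6, SOX1, NES) and 3 smooth muscle genes (ACTA2, TAGLN, CNN1) as log2(CPM + 1) on the vertical axis in the 9 groups on the horizontal axis, with each point 1 library and each line the mean of the 3 libraries on that scale. KDR was at 2092 CPM in endothelial cells in 2D, and TAGLN fell from 1339 CPM in smooth muscle cells in 2D to 139 CPM in PEG.

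In endothelial cells from alginate the markers PECAM1 and CDH5 were higher than in 2D, and KDR was lower. PECAM1 rose from 61.6 ± 5.26 to 155 ± 10.3 CPM (1.28 ± 0.08, adjusted p = 1.13e-20) and CDH5 from 340.2 ± 24.0 to 509.5 ± 9.72 CPM (0.53 ± 0.06), while KDR fell by 0.25 ± 0.04 on the log2 scale (2092 ± 30.5 to 1820.3 ± 22.7 CPM). ADCYAP1 and ADAMTS8, a metalloprotease, had 0 counts in 2D and were at least 213-fold and 62.6-fold higher in alginate. The neuropeptide precursor CARTPT was 355-fold higher (98.0 to 2938) and the leukotriene receptor CYSLTR2 218-fold (38.7 to 8641). The somatostatin receptor SSTR1 (7.39 ± 0.30) and the potassium channel KCNK17 (6.98 ± 0.31) rose as well. ANKRD1, a target of the YAP and TAZ coactivators, fell by 10.12 ± 0.15, from 892 ± 58.2 to 0.88 ± 1.39 CPM (adjusted p = 9.55e-53). The vasoconstrictor peptide gene EDN1 (-8.89 ± 0.20), the fibril-associated collagen COL12A1 (-7.53 ± 0.35) and the vesicle protein SYTL5 (-6.85 ± 0.36) fell too. The natriuretic peptide gene NPPB and SPP1 (osteopontin) were 675-fold (231 to 3275) and 220-fold (39.1 to 8729) higher in 2D. CARTPT had a log2 fold change of 8.17 with all libraries and 10.85 without EC 2D replicate 1, SSTR1 7.39 and 8.26 without EC 2D replicate 2, and CYSLTR2 7.27 and 9.14 without EC 2D replicate 2. NPPB had a log2 fold change of -9.27 with all libraries and -8.65 without EC alginate replicate 1 and -12.35 without EC alginate replicate 2, COL12A1 -7.53 and -6.91 without EC alginate replicate 1, and SPP1 -7.36 and -9.16 without EC alginate replicate 2. ANKRD1 had a log2 fold change of -10.12 with all libraries and -13.10 without EC alginate replicate 3 and SYTL5 -6.85 and -7.58 without EC alginate replicate 3.

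Among the fixed lists, 21 of 28 endothelial genes rose and 5 fell in alginate (median 1.27, adjusted p = 8.26e-07), with EMCN (3.95) and PLVAP (1.91) up and APLN (-2.72) down. Arterial genes rose in 12 of 14 and fell in 1 (median 1.13, adjusted p = 2.45e-06, with an estimated correlation adjusted p = 0.0787), for example CXCR4 (2.52) and GJA5 (3.03). Smooth muscle genes fell in 15 of 18 and rose in 1 (median -1.40, adjusted p = 8.37e-07), with TAGLN at -4.46 and MYL9 at -3.08, and epithelial genes fell in 11 of 12 (median -2.49, adjusted p = 2.45e-06), such as KRT8 (-4.16) and KRT18 (-4.35). All 24 mitosis genes fell (median -1.68, adjusted p = 2.52e-15), among them TOP2A (-1.84) and MKI67 (-1.40), as did 19 of 24 DNA replication genes (median -0.55, adjusted p = 2.45e-06). Cholesterol synthesis genes fell in 20 of 21 (median -0.72, adjusted p = 2.70e-08), for example FDFT1 (-1.53), and p53 targets in 15 of 20 with 1 rise (median -0.78, adjusted p = 5.96e-06). YAP and TAZ targets fell in 11 of 18 and rose in 3 (median -0.89, adjusted p = 0.0039, adjusted p = 0.0801 with an estimated correlation), with CTGF at -4.72 and CYR61 at -3.30. Markers of mesenchyme and pericytes rose in 12 of 17 and fell in 4 (median 0.31, adjusted p = 0.0238, adjusted p = 0.12 with an estimated correlation), among them the matrix genes POSTN (4.59) and DCN (6.45). Hypoxia genes had 7 higher and 11 lower of 24 (median -0.09, adjusted p = 0.752). The test passed 7546 of 13858 genes (3743 up, 3803 down, 2348 by 2-fold), and 15 of 38 lists passed, 7 of them with an estimated correlation.

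Endothelial cells from PEG had more transcript of hypoxia genes than those in 2D, alongside higher CDH5, KDR and PECAM1. CA9, a carbonic anhydrase induced in hypoxia, was 156-fold higher (52.9 to 757) at 28.1 ± 3.23 CPM. DKK2 was 214-fold higher (38.0 to 8491) and FAM153C, which has near-identical copies, 108-fold (29.4 to 894). The neurite genes NRN1 (6.28 ± 0.18, 134 ± 2.08 CPM in PEG) and RELN (6.38 ± 0.26) and the ephrin receptor EPHA3 (6.73 ± 0.41) rose. ANKRD1 (-6.37 ± 0.11), COL12A1 (-5.08 ± 0.27), SYTL5 (-5.26 ± 0.31), the homeobox gene LMX1B (-5.38 ± 0.34) and the extracellular superoxide dismutase SOD3 (-5.39 ± 0.52) fell. NNMT, a nicotinamide methyltransferase, was 175-fold higher in 2D (59.4 to 849). CDH5 (0.67 ± 0.06), KDR (0.29 ± 0.04, to 2605 ± 58.8 CPM) and PECAM1 (0.42 ± 0.09, adjusted p = 4.82e-05) rose. DKK2 had a log2 fold change of 7.27 with all libraries and 9.14 without EC 2D replicate 1, CA9 7.10 and 7.94 without EC 2D replicate 1 and 6.51 without EC 2D replicate 2, and EPHA3 6.73 and 7.95 without EC 2D replicate 1. NNMT had a log2 fold change of -7.31 with all libraries and -8.18 without EC PEG replicate 1 and -6.69 without EC PEG replicate 2 and SOD3 -5.40 and -6.54 without EC PEG replicate 2.

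In PEG 23 of 24 hypoxia genes rose in endothelial cells (median 2.24, adjusted p = 3.10e-16), with PFKFB4 (3.40), BNIP3 (2.72) and the glucose transporter SLC2A1 (2.36) among them. Glycolysis genes rose in 14 of 15, and adjusted over the list alone 14 rose and 1 fell (median 1.48, adjusted p = 1.30e-09, adjusted p = 0.188 with an estimated correlation), such as GPI (2.85) and PGK1 (2.39). Endothelial genes rose in 23 of 28 with CLDN5 (-1.56) lower (median 0.68, adjusted p = 5.60e-07, adjusted p = 0.0545 with an estimated correlation). Smooth muscle genes fell in 15 of 18 and rose in 1, or 2 adjusted over the list alone (median -1.78, adjusted p = 5.76e-07), with TAGLN at -4.63. All 24 mitosis genes fell (median -1.13, adjusted p = 1.63e-11), and cholesterol genes fell in 17 of 21 and rose in 1, or 18 and 2 adjusted over the list alone (median -0.47, adjusted p = 8.97e-05). Inflammatory genes fell in 11 of 16 and rose in 2 (median -0.88, adjusted p = 0.0019, adjusted p = 0.0862 with an estimated correlation), with CXCL1 (-2.66) down and PTGS2 (1.55) up. Ribosomal protein genes, whose reads may be shared with pseudogenes, rose in 21 of 24 by a median of 0.23 (adjusted p = 8.99e-04, adjusted p = 0.44 with an estimated correlation). The test passed 7858 genes (3976 up, 3882 down, 2487 by 2-fold), and of 14 lists called 4 passed with an estimated correlation.

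Endothelial cells from the 2 hydrogels differed in hypoxia genes. All 24 were lower in alginate than in PEG (median -2.02, adjusted p = 2.20e-17), for example PFKFB4 (-4.18) and NDRG1 (-3.25), the 1 list of 12 called that also passed with an estimated correlation. Glycolysis genes were lower in 14 of 15 (median -1.87, adjusted p = 1.55e-10, adjusted p = 0.187 with an estimated correlation). Interferon genes were higher in 8 of 11 (median 1.13, adjusted p = 0.0042, adjusted p = 0.0824 with an estimated correlation), such as BST2 (2.46) and IFIT1 (2.60). CARTPT had 0 counts in PEG and was at least 220.2-fold higher in alginate, CYSLTR2 was 101-fold higher (27.7 to 842), and the hormone gene SST was higher by 6.38 ± 0.34. FGF19, a growth factor gene, had 0 counts in alginate and was at least 62.8-fold higher in PEG, as was NPPB by 488-fold (167 to 2368), and EDN1 differed by -6.77 ± 0.25. PECAM1 was higher in alginate (0.86 ± 0.08) and KDR lower (-0.54 ± 0.04). CDH5 differed by -0.14 ± 0.05 (adjusted p = 0.026). This call was lost with no filter on low counts (0.064), with all libraries in the fit (0.22) and without alginate replicate 1 (0.13) or 3 (0.072) or PEG replicate 2 (0.118) or 3 (0.076), with adjusted p from 0.017 to 0.22 over the alternatives. The test passed 7755 genes (3842 higher, 3913 lower in alginate, 2324 by 2-fold). NPPB had a log2 fold change of -8.77 with all libraries and -8.15 without EC alginate replicate 1 and -11.85 without EC alginate replicate 2, SST 6.38 and 8.17 without EC PEG replicate 1, and CYSLTR2 6.41 and 5.81 without EC PEG replicate 2.

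Neural stem cells from alginate had far less transcript of hypoxia and glycolysis genes than those in 2D. All 22 hypoxia genes fell (median -3.70, adjusted p = 6.47e-11, adjusted p = 0.309 with an estimated correlation), with VEGFA, an angiogenic growth factor, at -4.35 and PFKFB3 at -4.62. All 15 glycolysis genes fell (median -2.41, adjusted p = 2.99e-08, adjusted p = 0.303 with an estimated correlation), with LDHA at -3.44. The neural markers moved apart. SOX1 rose from 8.24 ± 2.58 to 85.3 ± 5.71 CPM (3.40 ± 0.15, adjusted p = 2.20e-20) and NES from 295 ± 20.3 to 633 ± 23.3 CPM (1.10 ± 0.06), whereas PAX6 fell by 1.59 ± 0.07 (255 ± 10.7 to 84.5 ± 8.07 CPM). POU5F1 fell by 1.36 ± 0.24. The neural transcription factor genes OLIG3 and HES3 were 199.9-fold (35.6 to 7919.8) and 107-fold (29.4 to 887) higher in alginate, and C17orf51 had 0 counts in 2D and was at least 179.9-fold higher. MASP2, a protease of the complement system, rose by 6.06 ± 0.39, USP51, a deubiquitinase, stood at 10.9 ± 0.77 against 0.14 ± 0.24 CPM and LRRC55 was 56.2-fold higher (19.0 to 274). NPAS4, a transcription factor induced by neuronal activity, was 1734-fold (479 to 14323) and the antioxidant enzyme CAT (catalase) 861-fold (154 to 34063) higher in 2D. CRYZ, a quinone reductase, TYW3, a tRNA-modifying enzyme, and EDN2 (endothelin-2) had 0 counts in alginate and were at least 131-fold, 120.4-fold and 97.4-fold higher in 2D. CRYZ and TYW3 lie on opposite strands of chromosome 1 with starts 256 bases apart and overlap between these (GRCh38, GENCODE v29), so that their reads may be shared. The heat shock gene HSPA6, which has a near-identical copy, was 407-fold higher in 2D (72.4 to 16132). OLIG3 had a log2 fold change of 7.30 with all libraries and 9.48 without NSC 2D replicate 3, HES3 6.56 and 5.96 without NSC 2D replicate 3, and USP51 5.95 and 8.95 without NSC 2D replicate 3. LRRC55 had a log2 fold change of 5.69 with all libraries and 6.49 without NSC 2D replicate 3, NPAS4 -10.45 and -9.82 without NSC alginate replicate 3, and CAT -9.20 and -10.73 without NSC alginate replicate 3. HSPA6 had a log2 fold change of -8.12 with all libraries and -9.65 without NSC alginate replicate 3.

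The 18 neural stem genes had 8 higher and 7 lower in alginate (median 0.14, adjusted p = 0.745), and mitosis genes had 7 higher and 12 lower of 24 (median -0.15, adjusted p = 0.496). Forebrain genes rose in 10 of 13 and fell in 3 (median 0.89, adjusted p = 0.0383, adjusted p = 0.391 with an estimated correlation), with VAX1 (4.05) up and OTX1 (-3.92) and EMX2 (-2.86) down. DNA replication genes rose in 17 of 24 and fell in 4 (median 0.83, adjusted p = 0.0078, adjusted p = 0.403 with an estimated correlation), such as PCNA (2.94). Immediate early genes fell in 14 of 16 and rose in 1 (median -2.53, adjusted p = 5.27e-05, adjusted p = 0.151 with an estimated correlation), with JUN at -3.17 and ZFP36 at -4.19. Epithelial genes fell in 12 of 13 (median -2.28, adjusted p = 1.41e-04, adjusted p = 0.151 with an estimated correlation), for example CDH1 (-3.83). YAP and TAZ targets fell in 12 of 15 and rose in 3 (median -1.98, adjusted p = 5.50e-04, adjusted p = 0.303 with an estimated correlation), with CTGF at -7.20 and CYR61 at -5.91. All 8 histone genes fell (median -3.34, adjusted p = 6.47e-04, adjusted p = 0.164 with an estimated correlation). All 24 ribosomal protein genes fell (median -1.20, adjusted p = 3.39e-10, adjusted p = 0.235 with an estimated correlation). The test passed 9665 of 13368 genes (4945 up, 4720 down, 4528 by 2-fold), and of 17 lists called 0 passed with an estimated correlation. The alginate libraries differed from all others in composition. Their 100 top genes held 10.85% to 11.03% of counts, against 17.60% to 17.66% in 2D and at least 16.10% elsewhere. Their TMM factors over the 27 libraries were 1.2457 to 1.2533, against at most 1.0462 elsewhere. RLE size factors gave 9644 genes. How far the broad falls depend on composition was not tested.

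In smooth muscle cells from PEG the 3 contractile markers were lower than in 2D, and no list call of this comparison passed with an estimated correlation. TAGLN fell by 3.29 ± 0.10, from 1339 ± 10.5 to 139 ± 34.9 CPM (adjusted p = 7.82e-22). ACTA2 (-2.36 ± 0.12, from 741 ± 5.05 to 147 ± 56.2 CPM) and CNN1 (-2.42 ± 0.10) fell as well. Further falls were seen for LMOD1, an actin nucleator of smooth muscle (-4.70 ± 0.24), JPH2, a protein of muscle membrane junctions (-5.14 ± 0.31), HOXC9 (-5.21 ± 0.49), NIPAL4 (-5.08 ± 0.28) and CD274, the immune checkpoint ligand PD-L1 (-6.88 ± 0.35). ANKRD1 fell from 523 ± 11.9 to 16.6 ± 5.24 CPM. CA9 and the endothelial genes PPP1R16B and GJA4 had 0 counts in 2D and were at least 143-fold, 73.3-fold and 58.7-fold higher in PEG, and CD34, a surface marker of endothelial and blood progenitors, was 938-fold higher (168 to 37103) at 56.8 ± 2.33 CPM. NRN1 rose by 9.24 ± 0.24 and the kisspeptin receptor KISS1R was 294-fold higher (52.3 to 11636). POU5F1 rose by 3.79 ± 0.47 to 7.97 ± 0.50 CPM. CD34 had a log2 fold change of 9.42 with all libraries and 11.37 without VSMC 2D replicate 1, KISS1R 7.75 and 9.70 without VSMC 2D replicate 1, and NRN1 9.24 and 10.44 without VSMC 2D replicate 3. HOXC9 had a log2 fold change of -5.21 with all libraries and -6.49 without VSMC PEG replicate 2 and -4.63 without VSMC PEG replicate 3 and LMOD1 -4.70 and -5.40 without VSMC PEG replicate 3.

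Hypoxia genes rose in 23 of 24 and fell in 1 in PEG smooth muscle cells (median 2.52, adjusted p = 1.18e-11, adjusted p = 0.157 with an estimated correlation), with SLC2A1 at 4.28 and LOX at 3.83. Glycolysis genes rose in 13 of 15 and fell in 1 (median 1.64, adjusted p = 1.69e-06, adjusted p = 0.241 with an estimated correlation). Endothelial genes rose in 24 of 28 and fell in 4 (median 2.31, at the bound 2.01, adjusted p = 9.31e-05, adjusted p = 0.132 with an estimated correlation), with ESAM (4.83) and CDH5 (2.80) up and ANGPT2 (-1.74) and TEK (-1.18) down. All 14 epithelial genes rose (median 1.99, adjusted p = 7.84e-05, adjusted p = 0.132 with an estimated correlation), among them KRT19 (2.94) and CDH1 (2.30). In the same cells 5 of 5 endoderm and liver genes rose (median 2.24, adjusted p = 0.0127, adjusted p = 0.132 with an estimated correlation). Smooth muscle genes fell in 16 of 20 and rose in 2, or 17 and 2 adjusted over the list alone (median -1.51, adjusted p = 6.18e-07, adjusted p = 0.132 with an estimated correlation). All 24 mitosis genes fell (median -2.20, adjusted p = 6.45e-14, adjusted p = 0.132 with an estimated correlation), as did 23 of 24 DNA replication genes (median -1.78, adjusted p = 1.44e-10, adjusted p = 0.132 with an estimated correlation). Cholesterol genes fell in 20 of 21 and rose in 1 (median -1.39, adjusted p = 6.19e-08, adjusted p = 0.157 with an estimated correlation). PEG replicate 3 stood apart from replicates 1 and 2 toward day-1 alginate cells, with a fitted share of 15.1%. The test passed 9010 of 14064 genes (4870 up, 4140 down, 3613 by 2-fold), and 9040 without this library and day-1 alginate replicate 1. Of 16 lists called 0 passed with an estimated correlation.

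**Figure D2:**
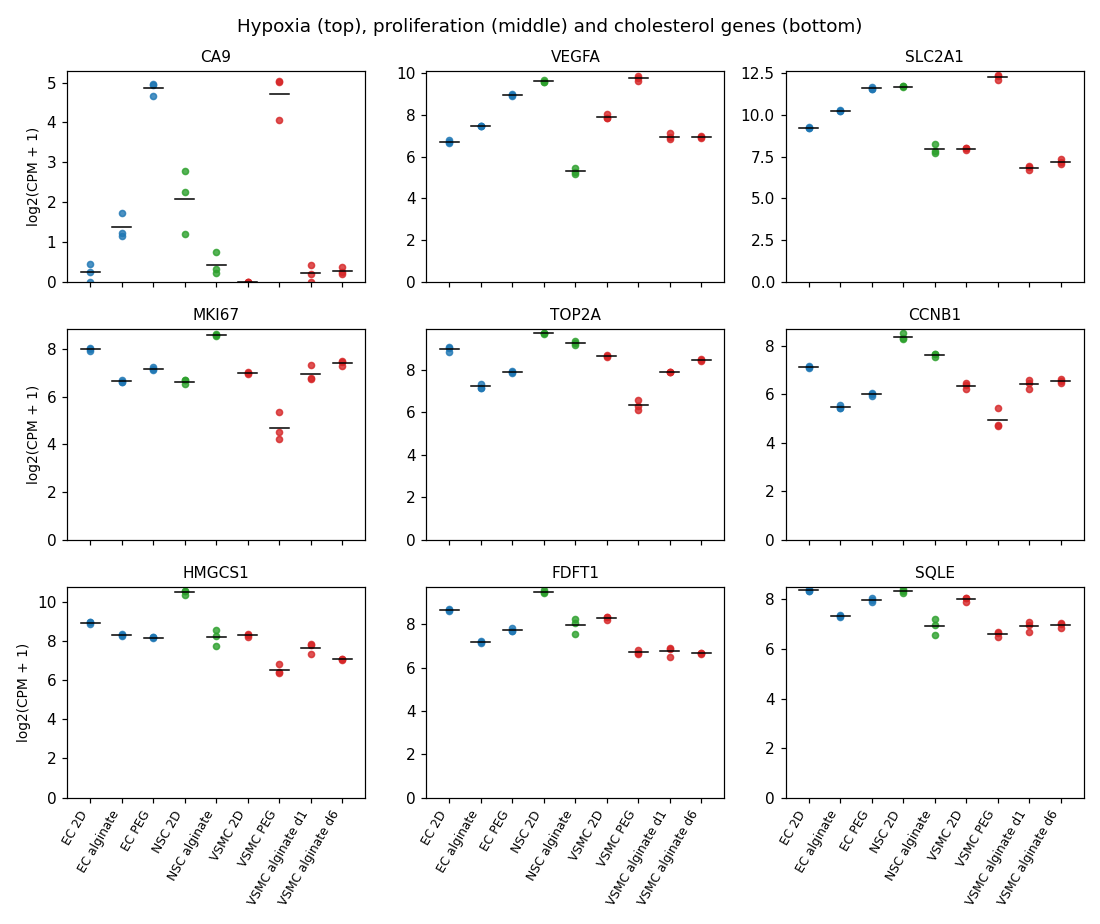
Levels of 3 hypoxia genes (CA9, VEGFA, SLC2A1), 3 division genes (MKI67, TOP2A, CCNB1) and 3 cholesterol genes (HMGCS1, FDFT1, SQLE) as log2(CPM + 1) on the vertical axis in the 9 groups on the horizontal axis, with each point 1 library and each line the mean of the 3 libraries on that scale. The genes were chosen for display after their values were seen, and CA9 stood at 28.1 CPM in endothelial and 26.3 CPM in smooth muscle cells from PEG.

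In smooth muscle cells on day 6 in alginate the 3 contractile markers were lower than in 2D, and no list call of this comparison passed with an estimated correlation. TAGLN fell by 2.54 ± 0.09 (1339 ± 10.5 to 233 ± 7.15 CPM, adjusted p = 1.76e-19). CNN1 (-2.57 ± 0.10) and ACTA2 (-1.15 ± 0.12, from 741 ± 5.05 to 339 ± 12.3 CPM) fell too. These markers were also lower than in 2D in endothelial and neural stem cells from alginate. Endothelial minus smooth muscle cells, the log2 fold changes differed by -4.22e-04 for ACTA2 and -0.03 for CNN1 (adjusted p = 0.920). For neural stem cells this was 0.19 (adjusted p = 0.685) and -0.16 (adjusted p = 0.578). None of these was called, and TAGLN fell more in both (-1.89 and -2.55). In smooth muscle cells the chemokine CXCL10 was 235-fold higher (80.1 to 1141), CD34 736-fold (132 to 29095), the vesicle gene SYT4 508-fold (90.9 to 20118) and UNQ6494 166-fold (29.5 to 6603). PENK, an opioid peptide precursor, rose by 6.66 ± 0.33 and GBP4, an interferon-induced GTPase, by 6.62 ± 0.25. NPPB fell by 6.37 ± 0.15, from 497 ± 12.1 to 6.03 ± 0.65 CPM. So did the epithelial cadherin CDH1 (-6.46 ± 0.37), the activin subunit INHBE (-5.83 ± 0.24), ANKRD1 (-5.71 ± 0.24), PNMA2 (-5.21 ± 0.34) and DERL3, a component of protein degradation at the endoplasmic reticulum (-5.19 ± 0.39). POU5F1 stood at 0.94 ± 0.25 against 0.54 ± 0.15 CPM (adjusted p = 0.304). CD34 had a log2 fold change of 9.07 with all libraries and 11.03 without VSMC 2D replicate 1, CXCL10 7.69 and 8.52 without VSMC 2D replicate 1, and GBP4 6.62 and 7.31 without VSMC 2D replicate 1. UNQ6494 had a log2 fold change of 6.93 with all libraries and 8.90 without VSMC 2D replicate 2, SYT4 8.53 and 10.49 without VSMC 2D replicate 3, and CDH1 -6.46 and -7.63 without day-6 replicate 2.

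On day 6 inflammatory genes rose in 17 of 18 and fell in 1 (median 1.94, adjusted p = 6.94e-09, adjusted p = 0.0771 with an estimated correlation), with CXCL12 (4.34) and CCL2 (1.92) up. Genes of the unfolded protein and ATF4 response fell in 19 of 20 (median -2.18, adjusted p = 5.05e-14, adjusted p = 0.0771 with an estimated correlation), such as ASNS (-3.60) and HERPUD1 (-2.86). Endothelial genes rose in 23 of 28 and fell in 2 (median 1.86, adjusted p = 5.42e-08, adjusted p = 0.0771 with an estimated correlation), with KDR at 1.40 and ERG at 4.98. Smooth muscle genes fell in 15 of 20 and rose in 1 (median -1.31, adjusted p = 1.95e-07, adjusted p = 0.105 with an estimated correlation). Hypoxia genes fell in 20 of 24 (median -0.95, adjusted p = 5.42e-08, adjusted p = 0.207 with an estimated correlation), for example ADM (-2.70), and glycolysis genes in 14 of 15 (median -0.78, adjusted p = 1.83e-06, adjusted p = 0.221 with an estimated correlation). Epithelial genes fell in 11 of 14 (median -1.74, at the bound -1.60, adjusted p = 8.36e-06, adjusted p = 0.0771 with an estimated correlation). Cholesterol genes fell in 18 of 21, or 19 adjusted over the list alone (median -1.11, adjusted p = 6.94e-09, adjusted p = 0.121 with an estimated correlation). Mitosis genes fell in 15 of 24 and rose in 1, MKI67 (0.41), with a median of -0.39 (adjusted p = 0.0056, adjusted p = 0.404 with an estimated correlation). The test passed 7501 genes (3781 up, 3720 down, 2383 by 2-fold), and of 19 lists called 0 passed with an estimated correlation.

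On day 1 in alginate, most smooth muscle genes of smooth muscle cells were lower than in 2D. Of 20, 13 fell and 3 rose, or 4 rose adjusted over the list alone (median -0.78, adjusted p = 0.0108, adjusted p = 0.295 with an estimated correlation). Among them DES fell (-3.70), and ACTG2 (4.79) and TPM1 (1.17) rose. ACTA2 stood at 848 ± 75.2 CPM against 741 ± 5.05 CPM (0.18 ± 0.11, adjusted p = 0.148). It passed the test without day-1 replicate 1 (0.26, adjusted p = 0.03), with no filter on low counts (adjusted p = 0.001), with only both groups in the fit (0.003) and without both libraries that stood apart (1.83e-07), with adjusted p from 1.83e-07 to 0.513 over the alternatives. TAGLN (-0.87 ± 0.09) and CNN1 (-2.43 ± 0.10) fell. GJA4 and the complement gene C7 had 0 counts in 2D and were at least 311-fold and 303-fold higher, and CD34 was 1544-fold higher (277 to 61031). PRPH, a neuronal filament gene, was 151-fold higher in 2D (41.5 to 1257), and CD274 (-6.23 ± 0.31) and CDH1 (-6.19 ± 0.35) fell. POU5F1 was 10.6-fold higher in 2D (1.47 to 465, log2 fold change -2.97, adjusted p = 0.012), a call lost without day-1 replicate 3 (-2.52, adjusted p = 0.051, range over the alternatives 0.009 to 0.051). Endothelial genes rose in 24 of 28 and fell in 3 (median 2.96, adjusted p = 9.85e-09, adjusted p = 0.0825 with an estimated correlation), with CDH5 at 3.98 and KDR at 1.28. Immediate early genes fell in 15 of 19 and rose in 2 (median -1.41, adjusted p = 6.89e-06, adjusted p = 0.0836 with an estimated correlation). Hypoxia genes fell in 21 of 24 and rose in 1 (median -1.28, adjusted p = 9.85e-09, adjusted p = 0.227 with an estimated correlation). The test passed 8872 genes (4356 up, 4516 down, 3135 by 2-fold), and 8620 without PEG replicate 3 and day-1 replicate 1. CD34 had a log2 fold change of 10.15 with all libraries and 12.11 without VSMC 2D replicate 1 and POU5F1 -2.97 and -4.72 without day-1 replicate 1.

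From day 1 to day 6 in alginate, smooth muscle cells gained transcript of several cytokine genes, and some contractile genes fell. Of 20 smooth muscle genes 11 fell and 3 rose (median -0.48, adjusted p = 0.0073, adjusted p = 0.394 with an estimated correlation). LTB (lymphotoxin beta) rose by 5.97 ± 0.24 to 46.8 ± 3.53 CPM (adjusted p = 1.17e-17), TNF by 5.37 ± 0.46, the lymphocyte activation gene CD69 by 4.23 ± 0.43, TNFRSF11B (osteoprotegerin) by 3.89 ± 0.36 and ISM1 by 3.85 ± 0.27. KLHL14 rose from 1.54 ± 0.77 to 24.5 ± 0.13 CPM. PRND had 0 counts on day 6 and was at least 137-fold higher on day 1, and GPR183, an oxysterol receptor, was 74.4-fold higher (25.1 to 363). The enteric smooth muscle actin ACTG2 (-6.04 ± 0.35), ACSM1 (-6.41 ± 0.53), COL12A1 (-5.89 ± 0.41), MAMDC2 (-5.02 ± 0.61), ACTA2 (-1.33 ± 0.11) and TAGLN (-1.67 ± 0.09) fell. CNN1 differed by -0.14 ± 0.11 (adjusted p = 0.319) and passed without day-1 replicate 1 (-0.26, adjusted p = 0.046) and without both libraries that stood apart (0.035), with adjusted p from 0.035 to 0.831 over the alternatives. POU5F1 was 18.5-fold higher on day 6 (2.92 to 769.6), at 0.94 ± 0.25 CPM. Pluripotency genes rose in 11 of 13, or 12 adjusted over the list alone (median 1.06, adjusted p = 6.55e-06), with L1TD1 (3.75) and LEFTY2 (2.97), the 1 list of 16 called that passed with an estimated correlation. Inflammatory genes rose in 14 of 18 and fell in 1, or 15 and 2 adjusted over the list alone (median 1.67, adjusted p = 5.93e-08, adjusted p = 0.0573 with an estimated correlation), such as ICAM1 (1.98). Endothelial genes fell in 16 of 28 and rose in 2, or 16 and 3 adjusted over the list alone (median -0.88, adjusted p = 0.0016, adjusted p = 0.232 with an estimated correlation). The test passed 6019 genes (3081 up, 2938 down, 1508 by 2-fold), and 5999 without PEG replicate 3 and day-1 replicate 1. ACSM1 had a log2 fold change of -6.41 with all libraries and -5.81 without day-6 replicate 1 and -8.12 without day-6 replicate 2, ACTG2 -6.05 and -7.07 without day-6 replicate 2, and MAMDC2 -5.02 and -4.42 without day-6 replicate 2 and -6.40 without day-6 replicate 3. GPR183 had a log2 fold change of -6.03 with all libraries and -6.93 without day-6 replicate 3, TNF 5.37 and 7.05 without day-1 replicate 1, and POU5F1 3.73 and 5.47 without day-1 replicate 1. TNFRSF11B had a log2 fold change of 3.89 with all libraries and 4.63 without day-1 replicate 3.

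Compared with PEG, smooth muscle cells from alginate were lower in epithelial genes on both days. On day 6 all 14 epithelial genes were lower (median -3.78, adjusted p = 2.65e-09), CDH1 by -8.76 ± 0.29 from 101 ± 17.8 CPM in PEG, and on day 1 all 14 as well (median -4.53, adjusted p = 8.08e-09). These calls passed with an estimated correlation. Hypoxia genes were lower in 23 of 24 on day 6, or 24 adjusted over the list alone (median -3.34, adjusted p = 1.39e-18, adjusted p = 0.112 with an estimated correlation), and in all 24 on day 1 (median -3.89, adjusted p = 2.26e-18, adjusted p = 0.118 with an estimated correlation). All 24 mitosis genes were higher on day 6 (median 1.85, adjusted p = 1.00e-13, adjusted p = 0.112 with an estimated correlation) and on day 1 (median 1.59, adjusted p = 7.37e-11, adjusted p = 0.186 with an estimated correlation). On day 6 the muscle ubiquitin ligase TRIM63 was 93.0-fold higher than in PEG (25.4 to 772), UNQ6494 (4.42 ± 0.47) and the tryptophan-degrading enzyme TDO2 (4.32 ± 0.17, 148 ± 3.18 CPM) were higher. DDIT4L had 0 counts and was at least 161-fold higher in PEG, and MAL2, a membrane trafficking gene, was 749-fold higher in PEG (134 to 29634). ACTA2 (1.21 ± 0.12) and TAGLN (0.75 ± 0.10) were higher on day 6 than in PEG, POU5F1 lower (-3.04 ± 0.41), and CNN1 differed by -0.15 ± 0.11 (adjusted p = 0.258). On day 1 NBPF7, which has near-identical copies, was higher by 4.14 ± 0.47 and SST by 3.75 ± 0.35. DDIT4L, SNCB and RIMKLA had 0 counts and were at least 165-fold, 140.1-fold and 123-fold higher in PEG. ACTA2 (2.54 ± 0.12) and TAGLN (2.42 ± 0.10) were higher on day 1 than in PEG, POU5F1 was 155-fold higher in PEG (27.3 to 6161), and CNN1 differed by -0.01 ± 0.11 (adjusted p = 0.943). The test passed 8333 genes on day 6 (4087 higher, 4246 lower, 2962 by 2-fold) and 9022 on day 1 (4606 higher, 4416 lower, 3413 by 2-fold), or 8427 and 8595 without PEG replicate 3 and day-1 replicate 1. TDO2 on day 6 had a log2 fold change of 4.32 with all libraries and 5.04 without VSMC PEG replicate 3, CDH1 on day 6 -8.76 and -9.93 without day-6 replicate 2, and MAL2 on day 6 -9.05 and -10.85 without day-6 replicate 3. NBPF7 on day 1 had a log2 fold change of 4.14 with all libraries and 6.20 without VSMC PEG replicate 3, SST on day 1 3.75 and 5.26 without VSMC PEG replicate 3, and POU5F1 on day 1 -6.77 and -8.51 without day-1 replicate 1.

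**Figure D3:**
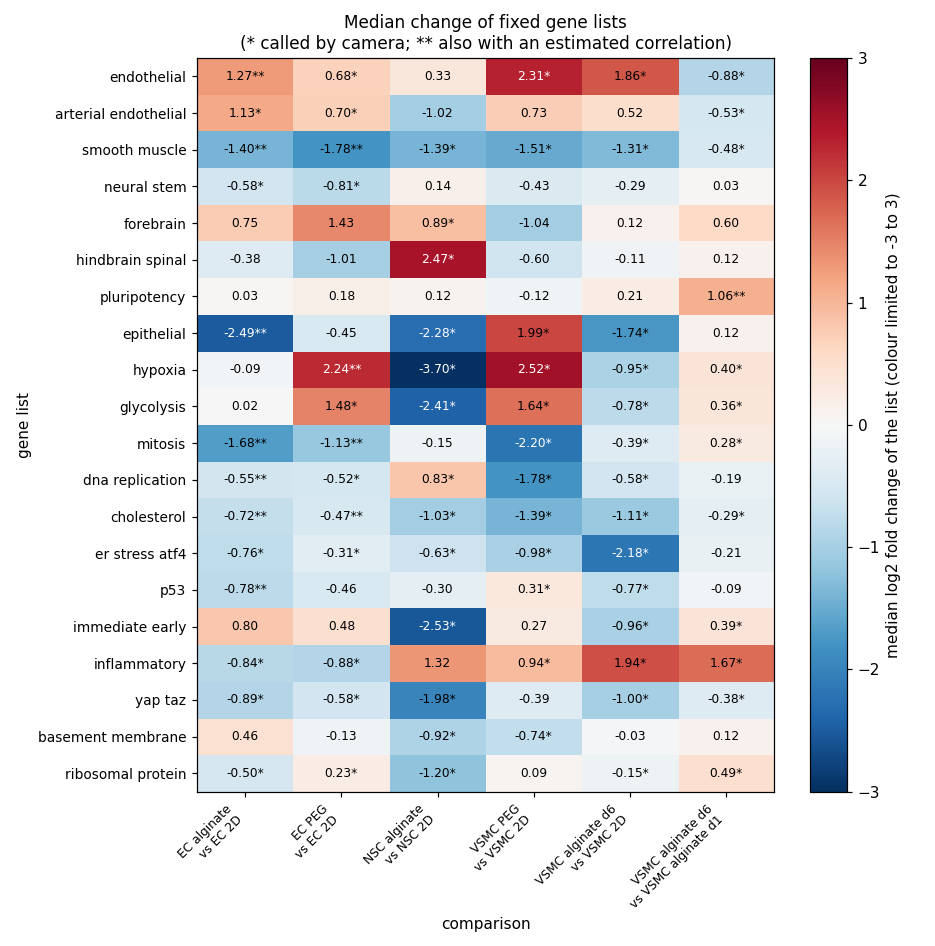
Median log2 fold change (colour) of 20 fixed gene lists (vertical axis) in the 6 main comparisons (horizontal axis), with 1 star for lists called by camera and a pair of stars for those also called with an estimated correlation. The hypoxia list had medians of 2.24 in endothelial and 2.52 in smooth muscle cells from PEG and -3.70 in neural stem cells from alginate.

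Changes were partly shared between hydrogels and between cell types. In endothelial cells 1993 genes rose and 2036 fell in both alginate and PEG, against 1073.9 and 1065.3 for independent calls (the product of both counts over the genes tested), and 1027 went opposite ways (2139.6). In smooth muscle cells 2411 genes rose and 2117 fell both on day 6 in alginate and in PEG (1309.3 and 1095.1), and 998 went opposite ways (2401.1). Each pair of comparisons used the same 3 control libraries, which cannot be split into parts of 2, so part of the excess may come from the shared controls. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.527 (rho = 0.480) in endothelial and r = 0.497 (rho = 0.489) in smooth muscle cells, where simulated data without any effect gave r = 0.501 and 0.509. The covariance was 0.512 and 0.604, against 0.0203 and 0.0232 in the simulations, which called 0 and 0.05 genes in both on average. Without shared controls, alginate against 2D raised 1825 and lowered 1961 genes in both endothelial and smooth muscle cells (day 6), against 979.8 and 1001.3 (r = 0.482, rho = 0.448 across genes), with ANKRD1 among those lowered. In this pair 856 genes went opposite ways (1981.9). Endothelial and neural stem cells shared 1500 raised and 1786 lowered genes (1192.9 and 1232.8, r = 0.168, rho = 0.206), and 1767 went opposite ways (2428.7). Neural stem and smooth muscle cells shared 1746 and 1752 (1222.2 and 1208.9, r = 0.268, rho = 0.285), and 1581 went opposite ways (2432.1).

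The change from 2D to hydrogel also differed between cell types when the difference itself was tested. Hypoxia genes changed more in the upward direction in endothelial than in neural stem cells from alginate in 23 of 24 (median difference 3.95, adjusted p = 6.05e-18), as did immediate early genes in 17 of 20 (median 2.69, adjusted p = 8.81e-09). For hypoxia genes the difference went with their fall in neural stem cells, since in endothelial cells from alginate the list was not called. Between endothelial and smooth muscle cells from alginate (day 6), all 24 mitosis genes differed (median -1.30, adjusted p = 3.25e-17) and 18 of 20 genes of the unfolded protein and ATF4 response, or 18 and 1 the other way adjusted over the list alone (median 1.07, adjusted p = 1.97e-12). In PEG, DNA replication genes differed in 22 of 24 with 1 the other way (median 1.29, adjusted p = 9.82e-11) and epithelial genes in 13 of 14 (median -2.36, adjusted p = 1.26e-08) between endothelial and smooth muscle cells. Histone genes differed between neural stem and smooth muscle cells from alginate in 6 of 8 (median -4.39, adjusted p = 5.52e-04). The tests of a difference passed 8718 genes for endothelial against neural stem cells, 5448 for endothelial against smooth muscle cells, 8418 for neural stem against smooth muscle cells (all in alginate) and 6703 for endothelial against smooth muscle cells in PEG. The last 3 set changes on different lanes against each other, and the lane cancels only if it acts alike on 2D and hydrogel libraries.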

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

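The tests below on the undetected genes of neural stem cells, on PEG replicate 3 and on endothelial genes in smooth muscle cells were chosen after the results were seen, and the splits of the libraries were planned. The results listed here passed a test of the difference between cell types in their change from 2D to a hydrogel. Values are differences of log2 fold changes, positive where the first-named cell type changed more in the upward direction, and for lists the median. Where a gene has at most 3 counts over a group, the value depends on the prior count and is no estimate of size. No counting interval was computed for these differences. CD34, SYT4 and PECAM1, for example, had 1 count over the smooth muscle libraries in 2D. Smooth muscle cells ran on another lane than the other two, so that a difference involving them carries the lane of both their groups, which cancels only if a lane acts alike on 2D and hydrogel libraries.

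For endothelial against neural stem cells in alginate 8718 genes differed. Lists that differed, also with an estimated correlation, were arterial (1.87), hypoxia (3.95), immediate early (2.69), basement membrane (1.05) and histone genes (3.12, at the bound 3.39). Genes were ADCYAP1 (14.60), HIST2H2BF (11.996), TYW3 (10.13), C17orf51 (-9.95), FLRT3 (-8.65), SLA (-8.01), KDR (-1.48), NES (-1.58) and CDH5 (-1.09, adjusted p = 0.041). The call for CDH5 was lost without EC 2D replicate 1 (0.055), NSC 2D replicate 1 (0.117), 2 (0.063) or 3 (0.088) and NSC alginate replicate 1 (0.056) or 2 (0.122), over a range of 0.009 to 0.122. PAX6 (2.21, adjusted p = 0.07) passed without EC 2D replicate 3 (5.41, adjusted p = 0.004, range 0.004 to 0.198). HIST2H2BF had a difference of 11.996 with all libraries and 11.39 without EC alginate replicate 2.

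For endothelial against smooth muscle cells in alginate (day 6) 5448 genes differed. Lists were lateral mesoderm (-0.78), epithelial (-0.49), mitosis (-1.30), the unfolded protein and ATF4 response (1.07), immediate early (1.64) and inflammatory genes (-2.57). Genes were ADCYAP1 (15.59), FOXA1 (7.60), SOST (-12.69), GPR116 (-8.28), TRIM63 (-8.15), CDH5 (-1.72), KDR (-1.62), PECAM1 (-5.53), TAGLN (-1.89) and ADAMTS8 (7.86, adjusted p = 0.028). The last call was lost without VSMC 2D replicate 3 (5.95, adjusted p = 1, range 0.001 to 1). TRIM63 had a difference of -8.15 with all libraries and -11.73 without VSMC 2D replicate 1, ADAMTS8 7.86 and 5.95 without VSMC 2D replicate 3 and 8.65 without day-6 replicate 2, and SOST -12.69 and -15.39 without VSMC 2D replicate 3. PECAM1 had a difference of -5.53 with all libraries and -7.44 without VSMC 2D replicate 3 and FOXA1 7.60 and 9.35 without day-6 replicate 1.

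For neural stem against smooth muscle cells in alginate (day 6) 8418 genes differed. Lists were inflammatory (-2.57, at the bound -2.92) and histone genes (-4.39). Genes were C17orf51 (10.85), CD274 (8.33), TRIM58 (8.09), HSPA6 (-12.52), CD34 (-10.99), NES (1.64), POU5F1 (-2.14), TAGLN (-2.55), SYT4 (-10.71, adjusted p = 0.021) and PAX6 (-2.02, adjusted p = 0.015). CD274, CD34 and SYT4 were near 0 in both groups of neural stem cells. They stood at 0.234, 0.141 and 0 CPM in alginate and at 0, 0.585 and 0.070 CPM in 2D. SYT4 was lost without NSC 2D replicate 3 (-8.53, adjusted p = 1, range 1.95e-06 to 1). PAX6 was lost without VSMC 2D replicate 3 (0.062) and day-6 replicate 2 (0.086) or 3 (0.055), over a range of 0.008 to 0.086. TRIM58 had a difference of 8.09 with all libraries and 11.11 without NSC 2D replicate 1 and 7.49 without NSC 2D replicate 3, CD34 -10.99 and -10.27 without NSC 2D replicate 3 and -12.90 without VSMC 2D replicate 1 and -11.69 without NSC alginate replicate 3, and SYT4 -10.71 and -8.53 without NSC 2D replicate 3 and -12.61 without VSMC 2D replicate 3. HSPA6 had a difference of -12.52 with all libraries and -14.27 without VSMC 2D replicate 1 and -14.18 without NSC alginate replicate 3.

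For endothelial against smooth muscle cells in PEG 6703 genes differed, and 6595 without PEG replicate 3 of the smooth muscle cells and day-1 replicate 1. Lists were lateral mesoderm (-0.48), epithelial (-2.36), DNA replication (1.29), mitosis (1.15), interferon (-0.89) and inflammatory genes (-1.90). Genes were DKK2 (9.89), IL16 (5.77), FGF19 (5.61), GJA4 (-9.37), CD34 (-8.81), PPP1R16B (-8.26), ACTA2 (0.94), CDH5 (-2.13), PECAM1 (-6.63), TAGLN (-1.34), CNN1 (0.59, adjusted p = 0.013) and KDR (-0.24, adjusted p = 0.015). CNN1 was lost without EC PEG replicate 3 (0.40, adjusted p = 0.13, range 0.001 to 0.13) and KDR without VSMC PEG replicate 3 (-0.18, adjusted p = 0.068, range 0.001 to 0.068). DKK2 had a difference of 9.89 with all libraries and 11.78 without EC 2D replicate 1, CD34 -8.81 and -10.72 without VSMC 2D replicate 1, and FGF19 5.61 and 4.76 without VSMC 2D replicate 2 and 7.75 without VSMC PEG replicate 3. PECAM1 had a difference of -6.63 with all libraries and -8.54 without VSMC 2D replicate 3 and IL16 5.77 and 6.65 without VSMC PEG replicate 3.

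Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave as many genes. The real counts were 7546 (EC alginate against 2D), 7858 (EC PEG against 2D), 7755 (EC alginate against PEG), 9665 (NSC alginate against 2D), 9010 (VSMC PEG against 2D), 7501 (day 6 against 2D), 6019 (day 6 against day 1), 8872 (day 1 against 2D), 8333 (day 6 against PEG), 9022 (day 1 against PEG), 11695 (EC against NSC), 7034 (VSMC against EC) and 11507 (VSMC against NSC). The highest count of the other splits was 0 by edgeR in all but the last, where it was 1. For the tests of a difference, fitted on 4 groups, 1 of 40 splits, the real one, gave as many genes. The real counts were 8676, 5757, 8499 and 6531 in the order above, and the highest others 5690, 2693, 5772 and 4343. Of the other splits, 8, 8, 6 and 6 kept the real groups of 1 cell type, and these gave at least 770, 1244, 639 and 519 genes. Splits that mixed the groups of both cell types gave 0. No split stands for cell types that change alike, so that these counts do not show whether chance can be excluded for the difference itself.

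In neural stem cells 8 genes of at least 10 CPM in 2D (CAT, CCDC152, CRYZ, DLX6, EDN2, HSPA6, NPAS4 and TYW3) had at most 3 counts over the alginate libraries, and CAT, CRYZ and TYW3 stood at 5 CPM or more in all other groups. Lower depth is argued against, since the alginate libraries held 1.17 times the counts of the 2D libraries. A loss that alginate brings to any cell type is argued against by the lowest log2 fold change of those genes expressed in 2D, -1.28 among 4 in endothelial cells and -0.48 among 3 in smooth muscle cells on day 6, where the neural stem cell medians of the same genes were -9.40 and -9.61. This test replaced a first version that fixed its own outcome and a second, on medians, that had too few genes to decide. Another starting culture, or a state of these cells in which the genes are off, may lie behind the pattern, and neither was tested. Genes also went the other way. C17orf51, OLIG3, HES3, USP51 and LRRC55 had at most 3 counts over the 2D libraries and at least 10 CPM in alginate. All genes of that direction were not counted by this rule.

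PEG replicate 3 of the smooth muscle cells lay between replicates 1 and 2 and the day-1 alginate libraries, with a fitted share of 15.1% (r = 0.753 across genes, which are not independent replicates), where every other library had at most 7.72%. A share of RNA or reads from day-1 cells is in line with the medians of 16.0% over 55 genes higher and 14.7% over 213 genes lower on day 1, a ratio of 1.09, whereas a proportional change of each gene is argued against by a ratio of 4.996 on the log2 scale (33.1% and 6.63%). A weaker hypoxic response is argued against, weakly, by a median share of 13.7% (quartiles 5.12% and 21.3%) over 24 genes that were flat between endothelial cells from alginate and PEG, a test that replaced one on 4 smooth muscle and 3 endothelial genes (medians 11.9% and 28.2%). Mixing of cells, RNA or libraries, or a culture in which part of the cells was in a state like that of day-1 alginate cells, may explain the pattern. Nothing in the labels separates these.

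Most of the 28 endothelial genes were higher in smooth muscle cells from hydrogels than in 2D. Some fell, and no list call of these comparisons passed with an estimated correlation. A fixed share of cells with the endothelial profile of the same hydrogel would raise all endothelial genes alike. Each would rise by 1 share of the distance from its 2D level to its endothelial level. The increments of the 23, 22 and 20 of 28 genes that had risen, with at least 10 CPM in the endothelial cells, were spread instead. The ratio of the 75th to the 25th percentile was 2.74 on day 1, 4.30 on day 6 and 3.20 in PEG. This argues against such a share as the only explanation. It cannot decide on a share along with changes within the smooth muscle cells, and the spread from counting error was not computed. Over the endothelial level alone, as the prediction had been worded, the ratios were 2.62, 2.96 and 2.73. KDR rose by 53.3%, 61.6% and 10.9% of this distance, CDH5 by 20.1%, 5.28% and 7.61% and PECAM1 by 18.7%, 6.09% and 13.2%, PLVAP was lowest with 2.75%, 0.902% and 2.03%, and the highest were S1PR1 (104%), ANGPT2 (207%) and MMRN1 (42.7%). Cells of another endothelial profile, a change within the smooth muscle cells, or an endothelial share with such a change may account for the pattern. None of these was tested.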

How the results depend on the processing

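The fits without 2 smooth muscle libraries and the further thresholds for undetected genes were chosen after the data were examined, and the other alternatives in this part were planned. All 486 alternative counts, of called genes and of calls by 2-fold, lay within 1.5 times the reported count. Those of called genes were at most 1.16 times apart from it. With the replicate number as a replicate block, the counts were 7507 (EC alginate against 2D), 7841 (EC PEG against 2D), 9582 (NSC alginate against 2D), 8930 (VSMC PEG against 2D), 7397 (day 6 against 2D), 5890 (day 6 against day 1), 7707 (EC alginate against PEG), 8810 (day 1 against 2D), 8274 (day 6 against PEG), 8933 (day 1 against PEG), 11666 (EC against NSC), 6977 (VSMC against EC) and 11477 (VSMC against NSC), and 8662, 5383, 8391 and 6636 for the tests of a difference. No pairing by number was seen in the residuals, since 0 of 30 pairs of libraries with the same number had residuals correlated above 0.1 (from -0.0684 to 0.0850). In 7 of 30 the correlation was highest with the same number, among them each replicate of day 6 against 2D (0.0197 to 0.0256). Residuals cannot show whether the libraries were paired by design. Leaving out 1 library gave 6926 to 7194 genes for EC alginate against 2D, 7186 to 7643 for EC PEG, 9211 to 9453 for NSC alginate, 8470 to 8843 for VSMC PEG, 6838 to 7044 for day 6 against 2D and 5206 to 5646 for day 6 against day 1.

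Of 268 list calls, 71 passed with an estimated correlation and 538 lists passed with fry, which compares a list with no other genes, so its count is not one of the same question. RLE size factors gave 269 calls and the replicate block 264. Genes shared between comparisons at a 2-fold change were fewer than at any size but above the counts for independent calls, given in brackets. Endothelial cells from both hydrogels shared 574 raised and 470 lowered genes (135.9 and 78.1), and smooth muscle cells 696 and 504 (172.8 and 134.1). Each of these pairs used the same control libraries. In alginate, endothelial and neural stem cells shared 267 and 222 (158.1 and 110.5). Endothelial and smooth muscle cells shared 411 and 441 (93.2 and 79.7), and neural stem and smooth muscle cells 353 and 320 (156.1 and 124.2). Fewer genes can pass the fold threshold, which lowers these counts by construction. Of 3187 values of named genes under the alternatives, 3160 kept their direction and their side of the threshold, 20 fell short of it and 7 passed it only there, and 0 changed direction. Of these 20, 18 came from leaving out 1 library. The cause was not tested for any of them. No alternative moved the median log2 fold change of a comparison by more than 0.0748, the shift with no filter on low counts for EC against NSC. In the simulated counts, with only 200 changed genes, 1.5-fold changes were found in 62.7%, 56.7% and 62.7% of genes. The real comparisons called far more genes, and the simulation held no broad shift in composition. These shares therefore need not hold for the real comparisons. An absent call still does not show an absent change of that size.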

Other observations

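The overlap in PEG and the counts of undetected genes in this part were chosen after the data were examined, whereas the list tests were planned and only picked for this part afterwards. Endothelial and smooth muscle cells changed alike from 2D to PEG in part of their genes. Of the genes tested in both, 2258 rose and 2121 fell in both (1321.2 and 1153.7 for independent calls), and 1144 went opposite ways, with r = 0.539 across genes, which are not independent replicates. NRN1 rose in both (6.28 ± 0.18 in endothelial and 9.24 ± 0.24 in smooth muscle cells, or 10.44 without VSMC 2D replicate 3), ANKRD1 fell in both, and the hypoxia genes SLC2A1 (2.36 and 4.28) and PFKFB4 (3.40 and 3.75) rose in both. No control library was shared between these comparisons.

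Genes of lateral mesoderm rose in 8 of 15 and fell in 3 in smooth muscle cells on day 6 in alginate against 2D, or 8 and 4 adjusted over the list alone (median 0.49, adjusted p = 0.0159, adjusted p = 0.105 with an estimated correlation), among them HAND1 (2.17) and HAND2 (2.27). Genes of the neural crest rose from day 1 to day 6 in 6 of 10, or 7 with 1 fall adjusted over the list alone (median 0.45, adjusted p = 0.0036, adjusted p = 0.0587 with an estimated correlation), such as SOX9 (1.87), and fell from 2D to day 1 in 7 of 10 (median -0.97, adjusted p = 0.0033, adjusted p = 0.0836 with an estimated correlation), SOX9 by -3.75. Interferon genes rose in 8 of 13 in smooth muscle cells from PEG (median 0.88, adjusted p = 0.0396, adjusted p = 0.181 with an estimated correlation), with HERC5 at 3.85, and in 7 of 13 with 1 fall on day 6 in alginate (median 0.95, adjusted p = 0.0119, adjusted p = 0.121 with an estimated correlation), with IFIT3 at 4.12. The list of housekeeping genes as a whole was called by camera in none of the 13 comparisons. Single members could still pass, as GAPDH did among the glycolysis genes that fell in neural stem cells from alginate.

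Genes with at most 3 counts over the libraries of 1 group and at 5 CPM or more in all other groups numbered 4 for neural stem cells in alginate and 1 for those in 2D. At 2 CPM the counts were 7 and 13, with 1 each for smooth muscle cells in 2D and on day 1, and at 10 CPM 1 and 0, so the order of the groups depends on the threshold.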
